A study of Mus musculus with 16 samples.

How the data were processed

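Gene expression was measured by RNA sequencing in B-1 and B-2 progenitors sorted from mouse E15.5 fetal liver, neonatal liver and adult bone marrow. Per the labels, the mice were C57BL6J, the liver samples came from males and females together, and the adult samples came from females. Cells were lysed directly after sorting, total RNA was taken with a Qiagen miRNAeasy micro kit, and libraries followed standard Illumina protocols. B-1 progenitors were sorted as lineage-negative CD93+ CD19+ CD45R− cells, and B-2 progenitors as lineage-negative CD93+ CD19− CD45R+ CD43+ cells. The lineage antibodies are not given in the sources used here. The design text places the neonates at day 2, and the age label at day 1.

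The deposited values are FPKM for 19182 protein-coding genes in 16 columns. Per the submitters' processing notes, STAR 2.3.0, HTSeq 0.5.4p3 and DESeq 1.12.1 were used with the mm10 (GRCm38) genome, without a statement of which tool made the FPKM. Gene positions are from GENCODE vM21, on the same build. Of the gene identifiers, 18862 were found there, and 18847 overlapped their annotated position. In the table, 1783 genes were at 0 throughout, and 32 gene names stood for more than 1 gene, so that genes were handled by identifier.

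Whole reads were recovered from the FPKM, because each gene's values in the columns are multiples of a common step. Recovery used genes with values above 0 in at least 3 columns and a tolerance of 0.1 read for a value called whole. It gave whole reads, or 0 throughout, for 17180 genes, which hold 98.64% of all nonzero values. Of the 10626 genes with a mean FPKM over 1, 6 had no recovered reads. On data simulated from the genes already recovered, with their own steps, 97.0% of genes were recovered, and 99.9% of the recovered values equalled the simulated reads. This does not test the assumption of a common step. Recovered totals were 4797834 to 8053615 reads per column. Read counts state counting error only.

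Each title stem has 2 numbered columns. Between the 2, genes with at least 50 reads summed over the pair varied by 1.04 to 1.08 times the counting noise, against 34.8 times between weeks 9 and 11 in B-1 and 61.3 times in B-2. The 2 numbered columns thus differed by about the sampling noise, and their mean was counted as 1 sample, here called a library. This left 8 libraries in 6 groups, with 1 library per lineage at E15.5, 1 per lineage in the neonate, and 2 per lineage in the adult (weeks 9 and 11). Recovered totals were 9622450 to 16019198 reads per library. The design fixed before the data were examined had counted 16 samples. The labels do not say whether the libraries came from separate animals, so the p-values measure only the spread between these samples. All residual spread came from the adult weeks, and a lone liver library is assumed to vary as the adult libraries did.

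Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with 1 mean per group, empirical Bayes moderation with a mean-variance trend, and 2 residual degrees of freedom. Genes with FPKM of at least 1 in at least 2 libraries were tested (11188 genes). All tests were two-sided, with Benjamini-Hochberg adjustment within each comparison, and a gene was called at an adjusted p under 0.05. The comparisons were B-1 against B-2 at each stage, each pair of stages within each lineage, and the difference of the B-1 against B-2 effect between stages. These comparisons, the form of the model, the filter thresholds, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Applying the model and the filter to 8 libraries in place of 16 samples was decided afterwards. A pair of comparisons was added after the calls had been counted. One compared B-1 with B-2 over 4 sets (E15.5, neonatal, week 9, week 11) as pairs, with the set as a fixed block. The other compared the 4 adult libraries with the 4 liver libraries, with the lineage in the model. It had no block for the set, so the B-1 and B-2 libraries of 1 set counted as independent, though stage varied only between sets. Differences between weeks 9 and 11 had a Pearson r of 0.43 between the lineages, so its p-values may be too small. The same week differences give the 2 residual degrees of freedom of the planned fits, which may thus not be fully independent.

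Gene lists were tested with camera in limma, with a preset correlation of 0.01 between genes and again with an estimated correlation. The estimate comes from the residuals, with 2 residual degrees of freedom in the planned fits, so that test had little power. Y-linked genes, at 0 in all adult libraries, had adjusted p = 0.16 (B-1) and 0.19 (B-2) with it for adult against E15.5. Failing it is thus not evidence that a list was unchanged. The preset correlation, in turn, treats the genes of a list as almost independent. Where they vary together between libraries, as plasmacytoid and myeloid markers did, its p-values may be far too small. Passing with the preset correlation alone is thus not strong evidence of a change. A list needed at least 3 tested members. The lists were the pro-B cell programme, multipotent and early lymphoid progenitor genes, the LIN28B and let-7 axis, imprinted growth genes, mature B-1 cell genes, mature B cell and MHC class II genes, cell cycle, interferon response, Toll-like receptors and NF-kappaB, cytokine and growth factor receptors, and homing and adhesion. Further lists were glycolysis, nuclear-encoded oxidative phosphorylation, cytosolic ribosomal proteins, and immediate early and stress genes. Lists of other cell types held myeloid, plasmacytoid dendritic cell, T/NK/innate lymphoid, erythroid, megakaryocyte and mast cell, hepatocyte, and stromal and endothelial markers. Y-linked genes served as a label check. A pair of lists of heavy chain V segments (D-proximal and D-distal) had 0 members in the table and were not tested, which left 23 lists.

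Named genes followed a rule. In the main comparisons (B-1 against B-2 at each stage, and adult against E15.5 in each lineage), they were up to 8 called genes in each direction with the largest log2 change. These had to have samples that did not overlap and a higher group mean of at least 5 FPKM. Immunoglobulin and T cell receptor segments, predicted genes, pseudogenes, small RNAs and the sort marker Cd19 were left out. Other comparisons had up to 4 in each direction, and the added pair up to 8. Up to 4 members of a list, those with the smallest p, and a fixed panel of 16 genes were added. The panel was Lin28b, Igf2bp3, Hmga2, Arid3a, Spi1 (Sfpi1 in the table), Ebf1, Pax5, Il7r, Crlf2, Flt3, Dntt, Rag1, Bhlhe41, Cd19, Cd93 and Spn.

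Length could not be used to compare genes. The gene length implied by FPKM and recovered reads had a Spearman rho of 0.003 with the annotated exon length across 7941 genes, which are not independent replicates. FPKM of different genes are therefore not comparable here. A gene's fold between libraries is unaffected, except through the added 1 and the filter. Standard errors and calls also depend on a gene's FPKM level, through the mean-variance trend, and so does the naming rule of at least 5 FPKM. For genes with few reads behind a high FPKM, reads are given instead of a fold. Where a group was at 0, the fold is a lower bound against a floor of 3 reads per library.

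Alternatives were a pseudocount of 0.1, no filter, a stricter filter (mean FPKM of at least 1), median-of-ratios scaling, quantile normalization, no trend, robust moderation, stage or week as a fixed block, only the groups compared, and leaving out each column. Chosen after seeing the data were all 16 columns as separate samples, leaving out each library or set, log2 CPM of recovered reads (0.5 added, genes with CPM of at least 1 in 2 libraries), and limma-voom on recovered reads. A count model of another package was planned for count tables and was not run, because the deposited values are FPKM.

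The pipeline was tested on simulated data with 100 genes changed by a fold of 2 and 100 by a fold of 8. At a fold of 8 it called 60% of genes at E15.5 and in the neonate, 93% in the adult, 78% for adult against E15.5 in B-1 and 79% in B-2. At a fold of 2 it called 0%, 0%, 4%, 0% and 0%. Calls among unchanged genes numbered 3 to 11 in these 5 comparisons. For the added comparisons, a fold of 2 was called in 45% (4 sets as pairs) and 73% (adult against liver), and a fold of 8 in 98% and 100%, with 8 and 14 calls among unchanged genes. The simulated spread was independent between libraries, was set to the moderated spread of the fit, and was the same for liver and adult libraries. Only genes above a set level of FPKM and reads were changed. The shares called may therefore be higher than in the real data. Figures and recovery used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.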

Results

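RNA of B-1 and B-2 progenitors was sequenced at 3 stages, E15.5 fetal liver, neonatal liver and adult bone marrow, to compare expression between the lineages and between the stages. B-1 progenitors are the precursors of the B cells that are made mainly before and around birth, and B-2 progenitors are those of conventional B cells. There were 8 libraries in 6 groups. Each liver group had 1 library, and each adult group had 2, of weeks 9 and 11. Library depth was 9622450 to 16019198 recovered reads. Log2 changes are on the log2(FPKM + 1) scale with their standard error, and folds are ratios of mean FPKM. FPKM of adults are means ± SD (n = 2), and liver groups have n = 1 and no SD. Calls, and their absence, are those of limma on log2(FPKM + 1) unless CPM of recovered reads or limma-voom is named. Adult and liver samples differed in stage, tissue and sex together, so none of these can be separated. The lineages were defined by gates that differ in CD19, CD45R and CD43. Differences between them, those of the pro-B cell programme included, cannot be separated from the choice of gate. The 4 Y-linked genes were at 0 in all 4 adult libraries, and Ddx3y was at 158 to 255 FPKM in the liver libraries, which matches the sex labels.

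At E15.5, B-1 progenitors had 42.4 times as much Lef1 as B-2 progenitors (240 against 5.67 FPKM, log2 change 5.18 ± 0.31, adjusted p = 0.043). Lef1 (ENSMUSG00000027985, chromosome 3, 131110471 to 131224356, GRCm38) encodes a transcription factor of early B cells that acts with Wnt signals. B-2 progenitors had more of 3 receptor and antigen-processing genes. Lifr (ENSMUSG00000054263, chromosome 15), the leukaemia inhibitory factor receptor, was at 2.73 FPKM in B-1 against 194 in B-2 (log2 change -5.71 ± 0.40). Lifr is also on the list of plasmacytoid dendritic cell markers. Nrp1, a semaphorin co-receptor, was 85.1-fold lower in B-1 (0.727 against 61.9 FPKM), and H2-DMa, which loads peptides on MHC class II, was 51.1-fold lower (1.23 against 63 FPKM). These genes and I830077J02Rik (-4.69 ± 0.34), which lies outside the naming rule and was chosen after its values were seen, had an adjusted p of 0.043.

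Those were the 5 calls at E15.5, 1 higher and 4 lower in B-1, while 1125 of 11188 genes had an unadjusted p under 0.05. Surrogate light chain genes were higher in B-1 short of the threshold, with Vpreb1 at 326 against 22.9 FPKM (3.77 ± 0.43, adjusted p = 0.06) and Igll1 at 2560 against 209 (3.61 ± 0.54, 0.095). Runx2 was at 8.17 against 695 FPKM (-6.25 ± 0.52, 0.054), and the plasmacytoid dendritic cell lectin Siglech at 0.15 against 77.4 (-6.09 ± 0.57, 0.054). The cytokine receptor gene Csf2rb2 (10.4 against 295 FPKM, 0.054), Ccr9 (1.18 against 84.1, 0.057), Mx1 (0.202 against 16.6, 0.057) and Klrd1 (0.672 against 63.3, 0.059) were also lower in B-1 and not called. On CPM, which gave 58 calls, Siglech (0.021), Runx2 (0.023), Csf2rb2, Ccr9 and Mx1 (each 0.026), Klrd1 (0.037) and Vpreb1 (0.04) were called, and Runx2 with limma-voom (0.046). Of the panel, Cd19 (4.07 ± 0.56, 0.078, and 0.049 on CPM), Hmga2 (-2.43 ± 0.40, 0.1), Flt3 (-3.77 ± 0.75, 0.14), Ebf1 (2.02 ± 0.50, 0.23) and Pax5 (57 against 24.4 FPKM, 0.27) were not called, and Cd19 differs by the sort itself. Each value rests on 1 library per lineage, assumed to vary as the adults did. The count was 0 without any 1 of the 4 adult libraries (B-1 or B-2, week 9 or 11), without a single column of B-1 week 9 (1 of its 2), B-2 week 9 (either) or B-2 week 11 (1 of its 2), or without the filter or the trend, 34 without the neonatal B-1 library, 2 with limma-voom, and 28 to 115 under 6 other settings of the 8 libraries, the highest with stage or week as a block.

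As lists, 12 of 23 passed at E15.5 with the preset correlation, and 0 with an estimated correlation. The pro-B cell programme was higher in B-1 (median log2 change 1.70, adjusted p = 4.7e-21). It had adjusted p = 0.33 with an estimated correlation, and of its 28 tested genes 1 was called, or 19 adjusted over the list alone. The list holds the sort marker Cd19, which is counted in its tallies at every stage. Plasmacytoid dendritic cell markers were lower (median -3.21, adjusted p = 1.5e-18, and adjusted p = 0.33 with an estimated correlation), with 1 of 17 called and 14 adjusted over the list alone. Erythroid markers were higher (median 2.70, adjusted p = 9.5e-11, and adjusted p = 0.33 with an estimated correlation), with 0 of 11 called and 9 higher and 1 lower adjusted over the list alone. Among them, Rhag was at 15.8 against 1 FPKM and Slc4a1 at 42.9 against 3.23. Interferon response genes (median -1.02, adjusted p = 2.4e-07), cytokine and growth factor receptors (-0.68, 5e-05), and homing and adhesion genes (-0.55, 0.0033) were lower, each with adjusted p = 0.33 with an estimated correlation. None of these had a called gene (1, 1 and 3 on CPM), and 6, 6 and 5 were lower adjusted over the list alone. Multipotent and early lymphoid progenitor genes were lower (-1, 6.9e-05, and adjusted p = 0.35 with an estimated correlation), with 0 called (1 on CPM and with limma-voom), and 1 higher and 7 lower adjusted over the list alone. On CPM, 3 pro-B cell genes and 6 plasmacytoid markers were called.

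Cell cycle genes were higher in B-1 at E15.5 (median 0.58, adjusted p = 3.9e-07, and adjusted p = 0.71 with an estimated correlation), as were imprinted growth genes (0.78, 0.0077, and adjusted p = 0.35 with an estimated correlation), with 0 genes of either called, also adjusted over the list alone. Mature B-1 cell genes (-0.70, 0.019), T/NK/innate lymphoid markers (-0.68, 0.004) and stromal and endothelial markers (-1.63, 0.0027) were lower, with 0 called (0, 1 and 0 on CPM) and 1, 4 and 3 lower adjusted over the list alone. With an estimated correlation, these 3 had adjusted p = 0.67, 0.55 and 0.44. The other 11 lists did not pass. They were the LIN28B and let-7 axis (median -0.15), mature B cell and MHC class II genes (-0.02, with H2-DMa called), Toll-like receptors and NF-kappaB (0.09, though mean -0.18 and test downward), glycolysis (-0.22), oxidative phosphorylation (0.01), ribosomal proteins (-0.26), immediate early genes (0.14), myeloid markers (-0.46), megakaryocyte and mast cell markers (-0.15, though mean 0.32 and test upward), hepatocyte markers (0, and 0.05 to 0.14 under the scaling alternatives) and Y-linked genes (-0.14).

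In the neonatal liver, 21 of 28 tested pro-B cell genes (Cd19, by the sort, among them) were called higher in B-1 progenitors, while 7 of 28 multipotent progenitor genes (1 other higher) and 7 of 23 myeloid markers were called lower. As lists, these had adjusted p = 0.58 with an estimated correlation. Lef1 was 989-fold higher in B-1 (159 against 0.16 FPKM, 7.10 ± 0.31, adjusted p = 0.015). The surrogate light chain genes Igll1 (ENSMUSG00000075370, 1890 against 11.5 FPKM, 7.24 ± 0.54, 0.017) and Vpreb1 (205 against 1.35, 6.45 ± 0.43, 0.017) were 165-fold and 152-fold higher, as were the lineage factor Pax5 (59.8 against 0.476, 5.36 ± 0.33) and Ebf1 (6600 against 291, 4.5 ± 0.50). Runx2 (ENSMUSG00000039153) was 237-fold lower in B-1 (3.28 against 776 FPKM, -7.50 ± 0.52, 0.017), and the progenitor receptor Flt3 143-fold lower (1.52 against 217, -6.43 ± 0.75, 0.021). Cd34, a stem and progenitor cell antigen, had 3 reads in B-1 against 3995 in B-2.

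Of 11188 genes, 463 were called in the neonate, 183 higher and 280 lower in B-1. Others with the largest rises in B-1 were Reln (387 against 0.868 FPKM, adjusted p = 0.043), Cplx2 (299 against 0.452, 661-fold, 0.017), Cacna1e (299 against 1.48), Ikzf3 (144 against 0.263) and Cacna2d1 (111 against 0.369). Lower in B-1 were Mpeg1 (8.69 against 1690 FPKM, -7.45 ± 0.62), Lair1 (2.73 against 483, -7.02 ± 0.69), Mn1 (0.6 against 186) and Hnf4a (3 against 512 reads). Of the panel, Hmga2 was lower (4.62 against 240 FPKM, -5.42 ± 0.40, 0.017), and Cd19 was higher by the sort (7.36 ± 0.56), while Bhlhe41 (3.73 ± 0.71, 0.055, and 0.046 on CPM) and Rag1 (4.28 ± 1.16, 0.11) were not called. Each value rests on 1 library per lineage, assumed to vary as the adults did. The count was 0 without the B-1 week 9 or the B-1 week 11 library, 212 with limma-voom (205 of them among the 463), 826 without the filter, and 1039 with stage or week as a block.

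In the neonatal comparison, 9 lists passed with the preset correlation, each with adjusted p = 0.58 with an estimated correlation. The pro-B cell programme was higher in B-1 (median 4.12, adjusted p = 6.3e-26), with 21 of 28 genes called and 23 adjusted over the list alone. Plasmacytoid dendritic cell markers were lower (median -3.13, 9.4e-11), with 10 of 17 called and 15 adjusted over the list alone, among them Siglech (0.101 against 72 FPKM) and Lifr (5.4 against 165). Cytosolic ribosomal protein genes were lower (median -1.05, 5e-08), with 0 called (1 on CPM) and 17 of 30 adjusted over the list alone. The median of all genes was -0.118 here and 0 to 0.043 under the scaling alternatives, so about 0.1 of such a median is a matter of scale. Myeloid markers (-1.98, 0.00013) had 7 genes called lower, and 7 adjusted over the list alone, with Csf1r at 0.481 against 61.8 FPKM. Multipotent progenitor genes (-1.23, 0.0008) had 1 higher and 7 lower (3 and 14 adjusted over the list alone). Interferon response genes (-1.15, 0.00039) had 3 lower (8 adjusted over the list alone), with Mx1 at 3.63 against 41.1 FPKM.

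T/NK/innate lymphoid markers were lower in neonatal B-1 cells (median -0.95, adjusted p = 0.015), with 3 called and 4 adjusted over the list alone, among them Klrd1 (0.676 against 142 FPKM) and Id2 (-4.29 ± 0.74, 0.043). Hepatocyte markers (1.14, 0.036, 4 tested genes) and imprinted growth genes (0.95, 0.009) were higher, with Alb called (12.1 against 0.745 FPKM), 3 hepatocyte genes and 2 imprinted genes adjusted over the list alone. These 3 lists also had adjusted p = 0.58 with an estimated correlation. Immediate early and stress genes did not pass (median -0.10, 0.04 and 0.06 under the scaling alternatives, mean -0.43, test upward), nor did cell cycle genes (median 0.34, mean -0.07, 0.55). Other called list members were S1pr1 (84.3 against 11.1 FPKM, 2.82 ± 0.31, 0.019), a receptor for egress from tissue, Il2ra (29.5 against 0.133, 4.75 ± 0.78, 0.039) and Tlr7 (-3.57 ± 0.56, 0.036).

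In adult bone marrow, 17 of 28 tested pro-B cell genes (again with Cd19) were called higher and 16 of 17 plasmacytoid dendritic cell markers lower in B-1 progenitors, and both lists had adjusted p = 0.48 with an estimated correlation. Lef1 was 23.5-fold higher in B-1 (263 ± 17.4 against 11.2 ± 1.07 FPKM, 4.44 ± 0.22, adjusted p = 0.011), Vpreb1 was higher by 4.09 ± 0.30 (403 ± 21 against 23.5 ± 8.68), and Pax5 by 2.89 ± 0.24 (67.1 ± 5.84 against 8.17 ± 0.899). Cplx2 (ENSMUSG00000025867), which acts in vesicle release, was 38.5-fold higher (239 ± 27.3 against 6.21 ± 2.38 FPKM). Siglech (ENSMUSG00000051504) was 131-fold lower in B-1 (1.31 ± 0.301 against 172 ± 84.9 FPKM, -6.14 ± 0.40, 0.011), and Runx2 50.8-fold lower (22 ± 10.3 against 1120 ± 215, -5.67 ± 0.37). Cd300c (-6.92 ± 0.41), Pacsin1 (-5.90 ± 0.28), Ccr9 (-5.37 ± 0.38) and Lifr (6.68 ± 0.231 against 283 ± 83.1 FPKM, -5.18 ± 0.28) were lower as well.

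Of 11188 genes, 555 were called in the adult, 204 higher and 351 lower in B-1. Others with the largest rises in B-1 were Sertad4 (81 ± 34.6 against 1.1 ± 1.25 FPKM), Cacna2d1 (97.4 ± 37.3 against 2.57 ± 0.743), Grb7 (26.8 ± 14 against 0.144 ± 0.0621), Smtnl2 (115-fold), Steap4 (47.4-fold) and Zkscan16 (316 against 3 reads). Slc41a2 (2.7 ± 1.5 against 207 ± 48.1 FPKM) and Havcr1 (156-fold) were lower. Of the panel, Ebf1 (3.23 ± 0.36, 0.014) and Cd19 (4.33 ± 0.40, by the sort) were higher and Flt3 was lower (6.4 ± 4.64 against 87.8 ± 34.3 FPKM, -3.69 ± 0.53, 0.026). Dntt (1.06 ± 0.53, 0.38), Rag1 (2.14 ± 0.82, 0.25) and Arid3a (-1 ± 0.22, 0.074) were not called. The count was 0 without the B-1 week 9 or the B-1 week 11 library, 321 without B-2 week 9 and 101 without B-2 week 11. It was 0 without the filter and 886 with stage or week as a block, 552 of the 555 among them.

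In the adult comparison, 9 lists passed with the preset correlation and 0 with an estimated correlation. Genes of the pro-B cell programme were higher in B-1 (median 2.37, adjusted p = 2e-18, and adjusted p = 0.48 with an estimated correlation), with 17 of 28 genes called and 21 adjusted over the list alone. Plasmacytoid dendritic cell markers were lower (median -3.99, 2.1e-20, and adjusted p = 0.48 with an estimated correlation), with 16 of 17 called, and 16 adjusted over the list alone. Multipotent progenitor genes (-0.66, 0.00071; 1 higher and 4 lower, 3 and 11 adjusted over the list alone), cytokine and growth factor receptors (-0.58, 0.00088; 4 lower, 2 higher and 8 lower adjusted over the list alone), homing genes (-0.33, 0.034; 1 higher and 6 lower, 2 and 10 adjusted over the list alone) and interferon response genes (-0.46, 0.045; 1 higher and 2 lower, 1 and 4 adjusted over the list alone) were lower. These had adjusted p = 0.48 with an estimated correlation. Csf2rb2 was at 22.9 ± 7.06 against 786 ± 96.4 FPKM, Mx1 at 4.33 ± 0.432 against 30.1 ± 6.11, and S1pr1, higher in B-1, at 78.4 ± 6.79 against 14.2 ± 0.877.

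Myeloid markers were lower in adult B-1 cells (median -0.55, adjusted p = 0.0012, and adjusted p = 0.81 with an estimated correlation), with 4 called and 6 adjusted over the list alone, among them Mpeg1 (154 ± 71.6 against 4640 ± 1840 FPKM). Their mean log2 CPM was 7.68 in B-1 against 9.32 in B-2 at week 9, and 6.66 against 7.05 at week 11. Some members, S100a9 among them, were higher in B-1 at week 11 (532 against 429 FPKM). Mature B-1 cell genes were lower too (-0.60, 0.034, and adjusted p = 0.81 with an estimated correlation), with Ahr called (1.49 ± 0.285 against 12.2 ± 2.32 FPKM) and 2 genes adjusted over the list alone. Cell cycle genes were higher (0.38, 0.0056, and adjusted p = 0.87 with an estimated correlation), with 0 genes called, also adjusted over the list alone. Toll-like receptor genes did not pass as a list, though Tlr7 (1.72 ± 0.426 against 30.7 ± 14.1 FPKM), Cd180 and Tlr9 were called lower. H2-DMa was lower (15.7 ± 1.85 against 84.2 ± 11.6 FPKM, 0.013), in a class II list with median -0.11 and mean 0.04. Glycolysis genes had a median of -0.07, which was 0.13 after quantile normalization.

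**Figure D1:**
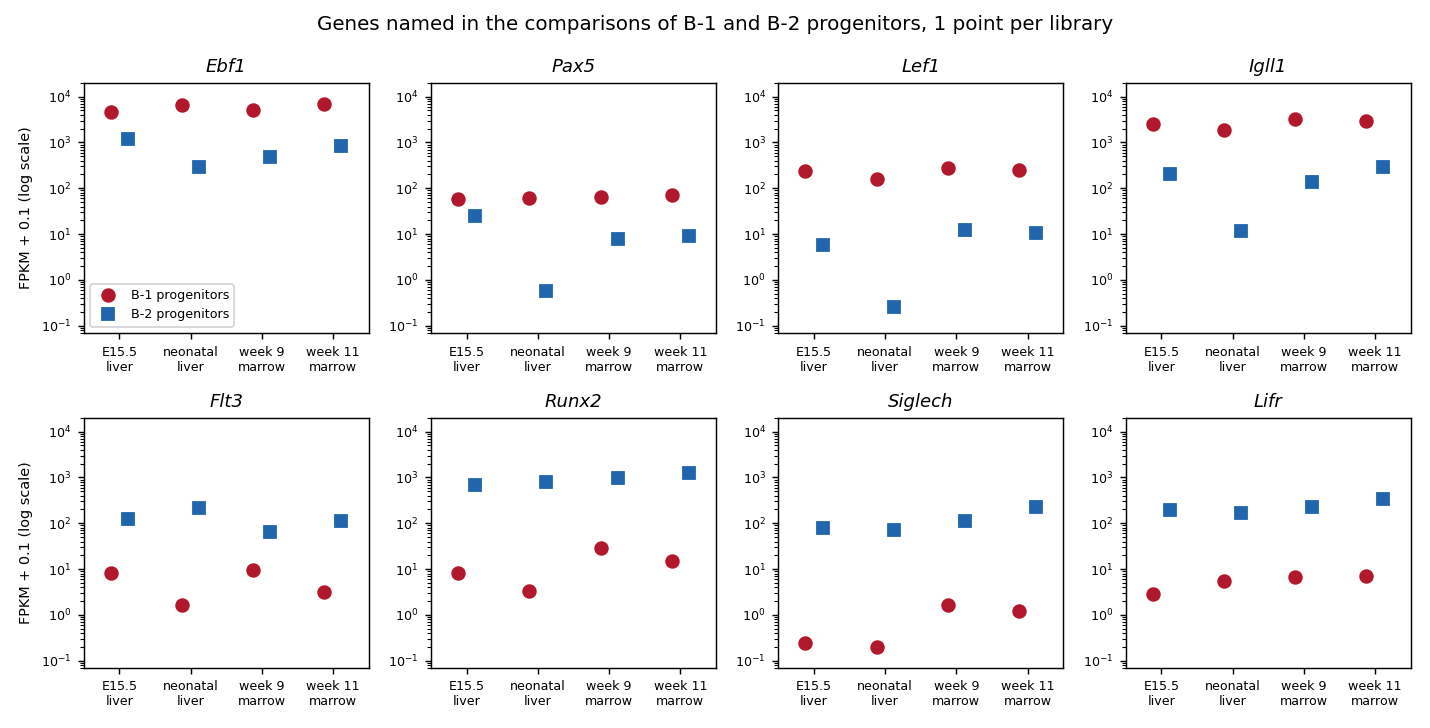
FPKM + 0.1 on a log axis of 8 genes that differed between the lineages, with 1 point per library at E15.5, neonate, week 9 and week 11, B-1 as red circles and B-2 as blue squares. Lef1 was above its B-2 level and Runx2, Siglech and Lifr below theirs in B-1 in all 4 sets, Lef1 at 159 FPKM in the neonate against 0.16.

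The 3 stages shared calls. All 5 genes called at E15.5 were called in the same direction in the neonate and the adult. Of the neonatal and adult calls, 96 were higher in B-1 in both (3.34 if independent) and 144 lower in both (8.78 if independent), and part of the excess may come from the shared estimate of spread. Over the 4 sets as pairs, a comparison added later, 679 genes were higher and 1088 lower in B-1. Runx2 was 66.9-fold lower (13.9 ± 11.3 against 927 ± 256 FPKM, n = 4 each, -6.27 ± 0.37, adjusted p = 9e-04), Siglech 171-fold lower (0.72 ± 0.708 against 123 ± 74.6) and Lifr 43-fold lower (5.37 ± 1.87 against 231 ± 77.3). Lef1 was 32.8-fold higher (231 ± 50.5 against 7.05 ± 5.31 FPKM, 5.29 ± 0.45, 0.002), Cplx2 51.8-fold, Sertad4 101-fold, Igll1 16.5-fold (2630 ± 555 against 160 ± 116) and Vpreb1 18.8-fold. Reln was higher too (142 ± 171 against 1.25 ± 0.957 FPKM, 0.012), with an SD above its mean. The count was 567 without B-2 week 11, 569 without B-1 week 11, and 948 without the filter.

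Over the 4 sets, 10 lists passed with the preset correlation and 0 with an estimated correlation. Again, the pro-B cell programme was higher in B-1 (median 2.77, adjusted p = 2.7e-16, and adjusted p = 0.41 with an estimated correlation), with 23 of 28 genes called, Cd19 among them, and 24 adjusted over the list alone. Plasmacytoid dendritic cell markers were lower (-3.35, 9e-15, and adjusted p = 0.36 with an estimated correlation), with 16 of 17 called, and 16 adjusted over the list alone. Interferon response genes were lower (-0.85, 0.00035, and adjusted p = 0.45 with an estimated correlation), with 1 higher and 10 lower, or 1 and 14 adjusted over the list alone. Genes known from mature B-1 cells were lower in B-1 progenitors (-0.68, 0.0057, and adjusted p = 0.36 with an estimated correlation), with 4 of 10 called, and 4 adjusted over the list alone. Of these 4, Spn encodes CD43, by which the B-2 cells were sorted, and the others were Ahr, Nfatc1 and Ccr1. Multipotent progenitor genes (-1.02, 0.00081, and adjusted p = 0.41 with an estimated correlation; 3 higher and 12 lower), cytokine receptors (-0.65, 0.00081, and adjusted p = 0.36 with an estimated correlation; 2 higher and 8 lower), myeloid markers (-1.03, 0.0072, and adjusted p = 0.72 with an estimated correlation; 6 of 23 lower), T/NK/innate lymphoid markers (-0.40, 0.011, and adjusted p = 0.45 with an estimated correlation; 4 of 17 lower) and ribosomal protein genes (-0.31, 0.039, and adjusted p = 0.88 with an estimated correlation; 0 called) were lower too, and cell cycle genes were higher (0.30, 0.00085, and adjusted p = 0.41 with an estimated correlation; 3 of 34 called).

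Between E15.5 and adult B-1 progenitors, Lin28b, Igf2bp1 and Hmga2 fell and Dntt and H2-K1 rose. Lin28b (ENSMUSG00000063804, chromosome 10, 45376620 to 45470201), which blocks let-7 maturation, was 381-fold lower in the adult (0.148 ± 0.209 against 56.3 FPKM, -5.65 ± 0.35, adjusted p = 0.013). The mRNA-binding gene Igf2bp1 had 1 read in the adults against 1096 at E15.5 (-5.49 ± 0.32), and the chromatin gene Hmga2 was 80.9-fold lower (0.358 ± 0.149 against 28.9 FPKM, -4.47 ± 0.34, 0.025). Dntt (ENSMUSG00000025014, chromosome 19, 41029275 to 41059523), which adds untemplated bases at V(D)J joints, was at 432 ± 0.256 FPKM in the adult against 0.173 (7 reads) at E15.5 (8.53 ± 0.65, 0.025). The class I gene H2-K1 was 14.9-fold higher (599 ± 28.6 against 40.2 FPKM, 3.86 ± 0.25, 0.016).

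In this comparison 11 genes were higher and 10 lower in the adult, of 11188. H2-Q6 was at least 2780-fold higher (568 ± 62.8 FPKM against 0), and H2-Q7 was at 129 ± 34.3 FPKM against 1 read, though these genes share reads with near-identical paralogs and their levels are uncertain. Ifi44 was at least 147-fold higher (41.8 ± 7.29 FPKM against 0, 5.41 ± 0.47, 0.039), Igj 234-fold, Ankrd33b 24.5-fold and Chd3 22.9-fold. Stfa1 was 128-fold lower (1.31 ± 0.331 against 167 FPKM), Ddx3y at least 223-fold and Eif2s3y at least 296-fold lower by sex, and Zfp423 had 0 against 24 reads. Olfr466 was at 0 against 10.2 FPKM, and had too few reads to be tested on CPM. Of the panel, Igf2bp3 was not called (-2.70 ± 0.33, 0.077). The E15.5 library stands alone and is assumed to vary as the adults did. The count was 0 without the B-1 week 9 or the B-1 week 11 library, 1 with limma-voom, 13 in a fit of these groups alone, 40 with robust moderation, and 42 without the filter, 2 of them higher and 40 lower.

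For adult against E15.5 B-1 cells, 19 lists passed with the preset correlation and 0 with an estimated correlation. Interferon response genes were higher in the adult (median 1.48, adjusted p = 5.6e-21, and adjusted p = 0.16 with an estimated correlation), with 1 of 27 called and 23 adjusted over the list alone. MHC class II and mature B cell genes were higher (1.52, 1.3e-11, and adjusted p = 0.26 with an estimated correlation), with 0 called (3 on CPM) and 8 adjusted over the list alone. Of these, Cd74 was at 177 ± 50.7 against 16.8 FPKM (0.061) and H2-DMa at 15.7 ± 1.85 against 1.23 (0.061), both called on CPM (0.039). The LIN28B and let-7 axis was lower (-1, 8.7e-10, and adjusted p = 0.16 with an estimated correlation), with 3 of 17 called and 7 adjusted over the list alone. Imprinted growth genes were lower (-2.01, 7.2e-08, and adjusted p = 0.22 with an estimated correlation), with Peg3 called (1 against 384 reads, -3.39 ± 0.32, 0.044) and 5 of 7 adjusted over the list alone. Cell cycle genes were lower (-0.85, 2.5e-12, and adjusted p = 0.40 with an estimated correlation), with 0 called, also adjusted over the list alone.

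Myeloid markers (median 1.93, adjusted p = 3.9e-11, and adjusted p = 0.34 with an estimated correlation), T/NK/innate lymphoid markers (1.37, 1.4e-08) and homing genes (0.37, 0.0041) were higher in adult B-1 cells, with 0 genes called and 11, 6 and 5 adjusted over the list alone. Toll-like receptor genes (0.89, 3.2e-06) were higher, with 0 called. The last 3 lists had adjusted p = 0.26 with an estimated correlation. Immediate early genes (1.87, 1.7e-09; 3 adjusted over the list alone) and mature B-1 cell genes (0.88, 0.0032) were higher, with 0 called, and had adjusted p = 0.40 with an estimated correlation. Fos was at 431 ± 145 against 14.1 FPKM (4.79 ± 0.91, 0.21). Erythroid markers were lower (-2.28, 3.1e-08, and adjusted p = 0.26 with an estimated correlation), with 0 called, and 1 higher and 7 lower adjusted over the list alone. Hepatocyte markers were lower (-1.44, 0.0032, and adjusted p = 0.34 with an estimated correlation), with 0 of 4 called (1 on CPM) and 3 adjusted over the list alone. Ribosomal protein genes (-0.39, 1.6e-06) and oxidative phosphorylation genes (-0.27, 0.0032) were lower, with adjusted p = 0.53 with an estimated correlation. The pro-B cell programme (0.31, 0.0096) and plasmacytoid markers (0.65, 0.0057) were higher, with adjusted p = 0.54 with an estimated correlation, and so were cytokine receptors (0.27, 0.045), with adjusted p = 0.34 with an estimated correlation. The Y-linked list was lower by sex (-4.23, 1e-11, and adjusted p = 0.16 with an estimated correlation), at a size that depends on the added 1.

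In B-2 progenitors Hmga2, Igf2bp1 and Lin28b also fell between E15.5 and the adult, and Igf2bp3, not called in B-1, was called lower. Hmga2 (ENSMUSG00000056758) was 272-fold lower in the adult (0.591 ± 0.268 against 160 FPKM, -6.68 ± 0.34, adjusted p = 0.0082). Igf2bp1 (ENSMUSG00000013415) was at least 290-fold lower (0 against 56 FPKM, -5.83 ± 0.32, 0.0082), Igf2bp3 24.7-fold lower (0.848 ± 0.176 against 20.9, -3.57 ± 0.33, 0.048), and Lin28b had 1 read against 1452 (-5.20 ± 0.35, 0.018). Dntt was 539-fold higher in the adult (240 ± 173 against 0.445 FPKM, 7.17 ± 0.65, 0.048), H2-D1 10.2-fold (663 ± 71.8 against 65, 3.33 ± 0.26, 0.031) and H2-K1 9.58-fold (404 ± 43.3 against 42.2). The antiprotease gene Slpi was 66.4-fold higher (102 ± 38.9 against 1.54 FPKM, 5.29 ± 0.49, 0.048).

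In B-2 cells 8 genes were higher and 8 lower in the adult. H2-Q6 was at least 710-fold higher (186 ± 21.4 FPKM against 0) and H2-Q7 was at 115 ± 32.1 FPKM against 1 read, with the same uncertainty from paralogs. Ankrd33b was at least 94.9-fold higher (24.4 ± 4.59 FPKM against 0). Ddx3y (at least 197-fold) and Eif2s3y (at least 292-fold) were lower by sex, Dytn had 0 against 17 reads, and Zfp423 had 0 against 3 reads. The B-1 and B-2 comparisons shared 6 genes higher in the adult (Dntt, H2-Q6, H2-Q7, H2-K1, H2-D1 and Ankrd33b; 0.00787 if independent) and 6 lower (Lin28b, Igf2bp1, Hmga2, Zfp423, Ddx3y and Eif2s3y; 0.00715 if independent), and part of the excess may come from the shared estimate of spread. The lone E15.5 library is assumed to vary as the adults did. The count was 0 without the B-1 week 9 or the B-1 week 11 library and in a fit of these groups alone, 3 with limma-voom, 8 without B-2 week 9, 43 without B-2 week 11, 33 with robust moderation, 40 without the filter (1 higher and 39 lower) and 25 on CPM.

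For adult against E15.5 B-2 cells, 17 lists passed with the preset correlation and 0 with an estimated correlation. The LIN28B and let-7 axis was lower in the adult (median -1.07, adjusted p = 1.2e-09, and adjusted p = 0.19 with an estimated correlation), with 4 of 17 called and 9 adjusted over the list alone. Interferon response genes were higher (0.93, 2.5e-09, and adjusted p = 0.19 with an estimated correlation), with 0 called and 2 adjusted over the list alone. Ribosomal protein genes (-0.75, 9.1e-09) and oxidative phosphorylation genes (-0.49, 0.00043) were lower, and immediate early genes (1.56, 7.3e-08; 3 adjusted over the list alone) were higher, with 0 called and adjusted p = 0.47 with an estimated correlation. Myeloid markers (2.38, 3.5e-09; 10 higher and 1 lower adjusted over the list alone), plasmacytoid markers (1.05, 6.7e-08; 2 adjusted over the list alone), MHC class II genes (0.92, 4.4e-06; 5 adjusted over the list alone) and T/NK/innate lymphoid markers (1.21, 0.00012; 3 adjusted over the list alone) were higher, and hepatocyte markers lower (-1.41, 0.0006; 3 adjusted over the list alone). These 5 lists had 0 genes called (on CPM 3 MHC class II genes and 1 hepatocyte gene) and adjusted p = 0.44 with an estimated correlation. S100a8 was at 1860 ± 1830 FPKM in the adult against 13.1 (6.57 ± 1.02, 0.12).

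Toll-like receptor genes were higher in adult B-2 cells (median 0.80, adjusted p = 3.6e-06, and adjusted p = 0.35 with an estimated correlation). Imprinted growth genes were lower (-1.13, 0.0007, and adjusted p = 0.40 with an estimated correlation), with 4 adjusted over the list alone, and so were cell cycle genes (-0.57, 4.4e-05, and adjusted p = 0.55 with an estimated correlation). Mature B-1 cell genes (0.98, 0.024) and erythroid markers (0.24, 0.02) were higher, with adjusted p = 0.47 with an estimated correlation, as were megakaryocyte and mast cell markers (1.52, 0.034, and adjusted p = 0.54 with an estimated correlation). Y-linked genes were lower by sex (-4.28, 5.1e-09, and adjusted p = 0.19 with an estimated correlation). The medians of the pro-B cell programme (-0.04, mean 0.28), the multipotent progenitor genes (-0.15) and the cytokine receptors (-0.06, mean 0.20) did not pass and were above 0 under median-of-ratios scaling (0.11, 0.01 and 0.10).

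**Figure D2:**
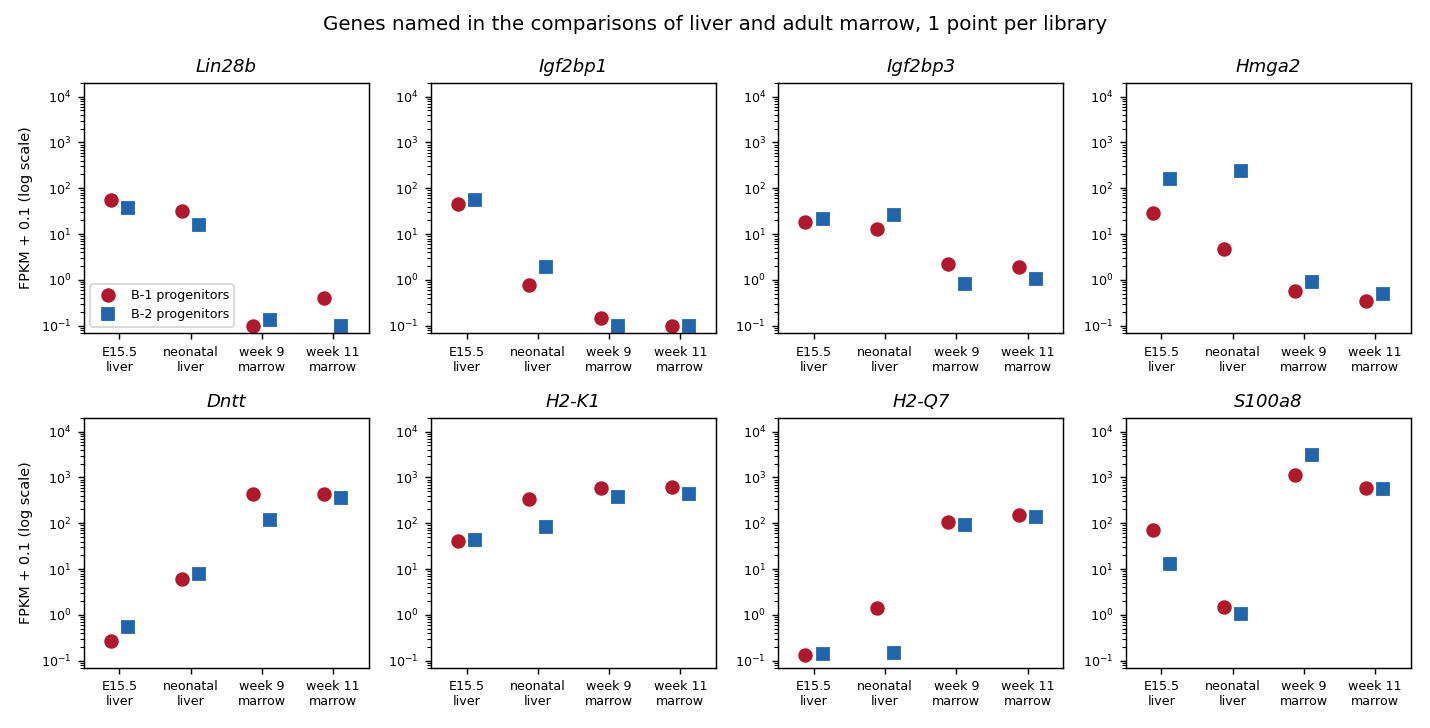
FPKM + 0.1 on a log axis of 8 genes that differed between the stages, with 1 point per library at E15.5, neonate, week 9 and week 11, B-1 as red circles and B-2 as blue squares. Lin28b was at 15.6 to 56.3 FPKM in the 4 liver libraries and at 0 to 0.295 in the 4 adult libraries, and Dntt at 0.173 to 7.72 and 118 to 432.

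Between E15.5 and the neonate, limma called 0 genes in either lineage, with 1230 genes in B-1 and 519 in B-2 at an unadjusted p under 0.05. On CPM the counts were 0 in B-1 and 1 in B-2, and with limma-voom 0 and 0. Without the filter they were 175 and 389. Each of these comparisons set 1 library against 1. In B-1, Igf2bp1 was at 0.66 against 44.9 FPKM (-4.79 ± 0.37, adjusted p = 0.1) and Hbb-b2 at 1.07 against 97.5 (-5.57 ± 0.64, 0.23). In B-2, Pax5 was at 0.476 against 24.4 FPKM (-4.10 ± 0.33, 0.16, and 0.034 on CPM) and Igll1 at 11.5 against 209 (-4.08 ± 0.54, 0.42). As lists in B-1, cell cycle genes (median -1.48, adjusted p = 1.6e-18, and adjusted p = 0.55 with an estimated correlation), erythroid markers (-3.07, 6.1e-11, and adjusted p = 0.40 with an estimated correlation) and myeloid markers (-2.16, 1.2e-07, and adjusted p = 0.55 with an estimated correlation) were lower in the neonate, with 25, 9 and 0 genes adjusted over the list alone. In B-2, the pro-B cell programme (-1.51, 3.6e-18, and adjusted p = 0.59 with an estimated correlation) and cell cycle genes (-1.07, 3.3e-11, and adjusted p = 0.79 with an estimated correlation) were lower, with 1 higher and 13 lower, and 9 lower, adjusted over the list alone. Erythroid markers (-1, 3.5e-05) and hepatocyte markers (-1.16, 0.00018) were lower in neonatal B-2 cells too, both with adjusted p = 0.59 with an estimated correlation, and immediate early and stress genes were higher in B-2 (1.24, 1.7e-05, and adjusted p = 0.79 with an estimated correlation) and in B-1 (0.87, 0.00089, and adjusted p = 0.62 with an estimated correlation). In all, 14 lists in B-1 and 10 in B-2 passed with the preset correlation, and 0 with an estimated correlation. Interferon response genes were higher in both lineages (0.73, 1.8e-07 and 0.92, 7.6e-12), with adjusted p = 0.40 and 0.34 with an estimated correlation, and 0 and 2 genes adjusted over the list alone.

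Between the neonate and the adult, 3 genes were higher and 6 lower in B-1, and 14 higher and 13 lower in B-2. In B-1, Igj was 330-fold higher (50 ± 14.7 against 0.152 FPKM, 5.44 ± 0.41, adjusted p = 0.035), H2-Q7 97.3-fold and H2-Q6 21.4-fold higher, and Lin28b was lower (0.148 ± 0.209 against 31.2 FPKM, -4.82 ± 0.35, 0.03). In B-2, Hmga2 was 405-fold lower (0.591 ± 0.268 against 240 FPKM, -7.25 ± 0.34, 0.0051), and Lin28b (-4.03 ± 0.35, 0.03) and Igf2bp3 (-3.86 ± 0.33, 0.03) were lower. Of 17 tested mature B cell and MHC class II genes, 3 were called, all higher in adult B-2 cells (list median 0.76, adjusted p = 7.2e-05, and adjusted p = 0.57 with an estimated correlation). They were H2-Aa at 61.6 against 3.37 FPKM (3.83 ± 0.33, 0.03), Cd74 at 375 against 26.3 (3.77 ± 0.35, 0.036) and H2-Ab1 at 41.7 against 3.04 (3.40 ± 0.29, 0.03). Slpi was 126-fold and H2-Q6 948-fold higher, H2-Q7 had 4383 against 1 reads and Smagp 40 against 0 reads. Lef1 was higher in adult B-2 cells (11.2 ± 1.07 against 0.16 FPKM, 3.39 ± 0.27, 0.03). Ddx3y and Eif2s3y were lower by sex in both lineages, with adult levels of 0. Zfp423 and Glyat, also called lower, had 2 reads each in B-1, and 5 and 2 in B-2.

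The neonatal libraries stand alone and are assumed to vary as the adults did. The count for B-1 was 0 without the B-1 week 9 or the B-1 week 11 library, 43 without B-2 week 9, 46 without B-2 week 11, 0 with limma-voom, 73 with a pseudocount of 0.1 (60 higher and 13 lower), 43 on CPM (34 and 9) and 180 without the filter (5 and 175), so that the balance of directions depends on the setting. For B-2 it was 0 without B-1 week 9 or 11, 8 without B-2 week 9, 79 without B-2 week 11, 42 without B-1 neonatal, 43 without B-1 E15.5, 0 in a fit of these groups alone, 1 with limma-voom and 574 without the filter (43 higher and 531 lower). Of the lists, 15 passed in B-1 and 12 in B-2 with the preset correlation, and 0 with an estimated correlation. Among them, myeloid markers were higher in adult B-1 cells than in neonatal ones (median 4.16, adjusted p = 3.1e-24, and adjusted p = 0.34 with an estimated correlation), with 0 called (6 on CPM) and 21 of 23 adjusted over the list alone. In B-2 they were higher too (2.07, 5.7e-08), with 0 called (2 on CPM) and 9 higher and 1 lower adjusted over the list alone. The pro-B cell programme (2.15, 6.7e-14; 17 higher and 1 lower adjusted over the list alone) was higher and ribosomal protein genes (-0.93, 7.5e-12; 17 adjusted over the list alone) were lower in adult B-2 cells. These 3 had adjusted p = 0.57 with an estimated correlation. Other markers of other cells were higher too, T/NK/innate lymphoid (1.54 in B-1 and 1.21 in B-2), erythroid (1.36 and 1.24), plasmacytoid (0.26 and 0.84) and megakaryocyte and mast cell ones (1.15 and 1.77), with adjusted p of 0.34 to 0.66 with an estimated correlation. The LIN28B and let-7 axis was lower in both lineages, with adjusted p = 0.27 (B-1) and 0.30 (B-2) with an estimated correlation (-0.61, 6e-06 and -1.47, 1.5e-08), and 4 and 9 genes adjusted over the list alone.

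Over both lineages, a comparison added later, 241 genes were higher and 49 lower in the 4 adult libraries than in the 4 liver libraries. The B-1 and B-2 libraries of 1 set counted as independent here, so the p-values may be too small and the calls too many. Lin28b was 425-fold lower (0.0819 ± 0.143 against 34.8 ± 16.8 FPKM, -4.92 ± 0.32, adjusted p = 0.00029), Igf2bp3 13.9-fold lower (1.39 ± 0.647 against 19.4 ± 5.5, -3.09 ± 0.28, 0.0014), Hmga2 229-fold and Ptk7 30.6-fold lower. Neutrophil granule genes were among the largest rises, with Ngp at 677 ± 655 against 4.49 ± 6.22 FPKM (7.05 ± 0.87, 0.0061), S100a9 at 1260 ± 1150 against 18.8 ± 30.2, S100a8 at 1360 ± 1230 against 21.9 ± 34, and Retnlg at 188 ± 146 against 0.362 ± 0.247. Myeloid markers passed as a list (median 2.42, adjusted p = 1.5e-16, and adjusted p = 0.20 with an estimated correlation), with 10 of 23 called and 18 adjusted over the list alone. In all, 17 lists passed with the preset correlation and 0 with an estimated correlation. Among markers of other cells, T/NK/innate lymphoid (1.22, 1.6e-08, and adjusted p = 0.20 with an estimated correlation; 5 of 17 called), plasmacytoid (0.64, 1.4e-07, and adjusted p = 0.20 with an estimated correlation; 2 of 17 called) and megakaryocyte and mast cell markers (1.37, 0.0036, and adjusted p = 0.32 with an estimated correlation; 2 higher and 1 lower) were higher too, and hepatocyte markers lower (-1.12, 0.0077, and adjusted p = 0.23 with an estimated correlation; 2 of 4 called). The LIN28B and let-7 axis was lower (-0.70, 1.9e-09, and adjusted p = 0.10 with an estimated correlation), with 6 called, and 1 higher and 11 lower adjusted over the list alone. The count was 854 without the B-1 neonatal library (433 higher and 421 lower, so that the excess of rises depends on that library), 104 without B-2 E15.5, 191 without B-1 E15.5 or B-2 neonatal, 138 without B-1 week 9 and 150 without B-1 week 11. It was 115 without the filter and 454 on CPM.

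Of the panel, 5 genes were called in none of the 5 main comparisons or the added ones, apart from Bhlhe41 on CPM in the neonate. They were Il7r (48.6 to 193 FPKM over the 8 libraries), Cd93 (167 to 508), Crlf2 (1.65 to 3.86), Bhlhe41 (0.114 to 13.7) and Spi1, listed as Sfpi1 (6.05 to 22.7). Spn, which encodes the sort marker CD43, was at 20.2 to 66.2 FPKM in B-1 and 56.4 to 103 in B-2 libraries and was called only in the added comparisons.

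The difference of the B-1 against B-2 effect was tested as an interaction. For adult minus E15.5, limma called 0 genes, with 287 at an unadjusted p under 0.05, and for neonatal minus E15.5 it called 0, with 491. Log2 CPM and limma-voom called 0 in both, as did a fit with stage or week as a block. Without the filter, 353 genes were called for neonatal minus E15.5. So an effect called at 1 stage and not at another is not shown to differ for any single gene. As lists, 7 and 8 passed with the preset correlation, and 0 with an estimated correlation.

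**Figure D3:**
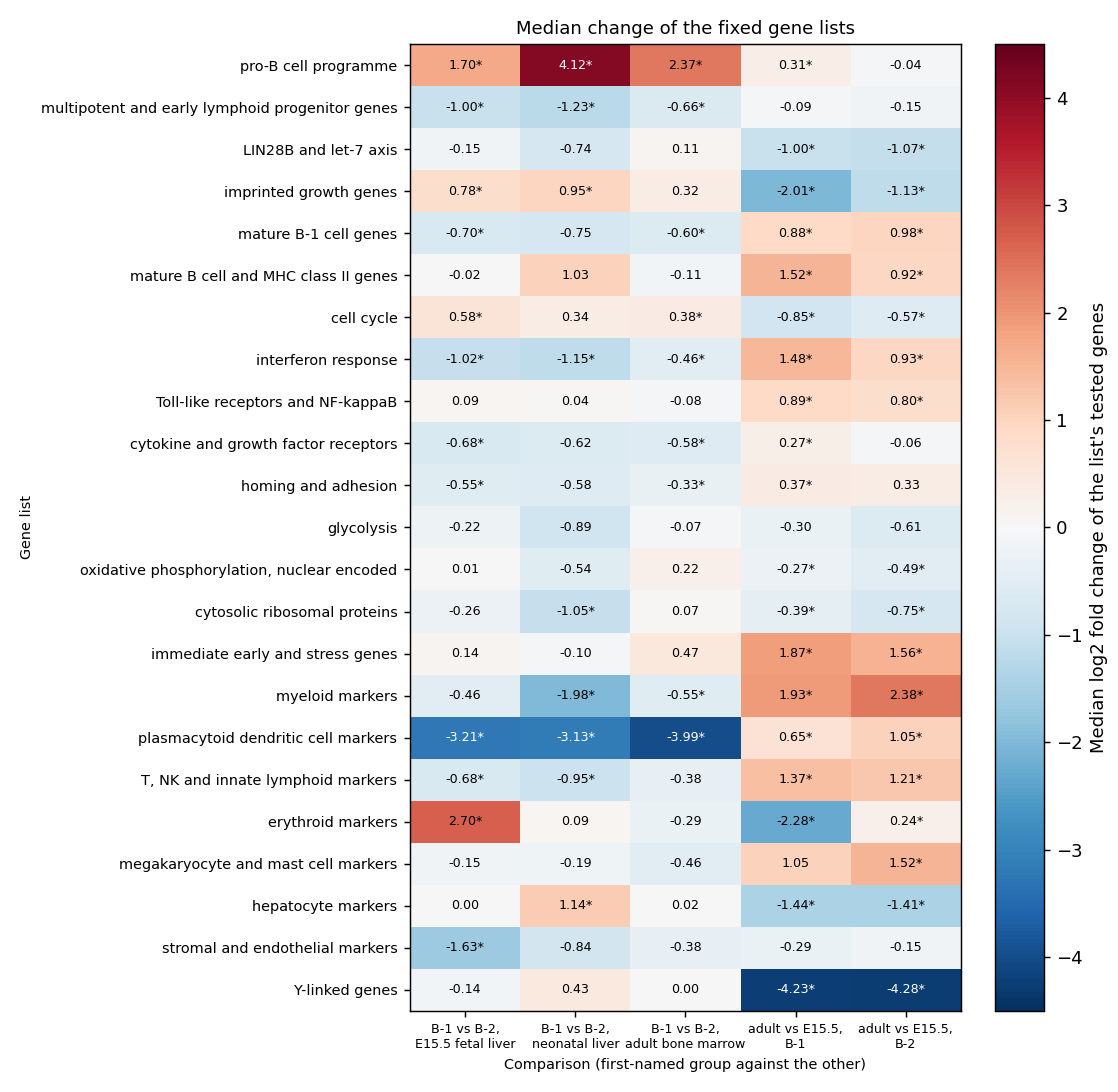
Median log2 change of the tested genes of 23 lists in 5 comparisons, as coloured cells, B-1 minus B-2 at the 3 stages and adult minus E15.5 in each lineage, where a star marks an adjusted p under 0.05 with a preset correlation of 0.01. The pro-B cell programme stands at 1.70, 4.12 and 2.37 between the lineages and plasmacytoid markers at -3.21, -3.13 and -3.99, while no list passed with an estimated correlation, and small medians change sign with scaling (adult glycolysis -0.07 to 0.13, neonatal immediate early genes -0.10 to 0.06, and for adult against E15.5 in B-2 the pro-B programme -0.04 to 0.11, multipotent genes -0.15 to 0.01 and cytokine receptors -0.06 to 0.10).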

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

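Of the tests in this part, those on other cell types and depth, and the limit to splits that keep the blocks of the model, were chosen after the results were seen, while the tests of the difference between stages and of other splits were not, though both comparisons that were split were added later.

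The B-1 against B-2 effect differed between stages for 15 results of lists, by an interaction test with a preset correlation, and for 0 lists with an estimated correlation or single genes. Mean log2 differences are given. From E15.5 to the adult, the effect moved down for erythroid markers (-2.36, adjusted p = 5.3e-20, and 0.47 with an estimated correlation) and plasmacytoid dendritic cell markers (-0.63, 6.6e-05, and 0.92). It moved up for interferon response genes (0.65, 8e-05, and 0.47), the LIN28B and let-7 axis (0.44, 0.046, and 0.83) and ribosomal protein genes (0.28, 0.014, and 0.92). It moved down for imprinted growth genes (-0.42, 0.036, and 0.83) and cell cycle genes (-0.18, 0.028, and 0.92).

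From E15.5 to the neonate, the effect moved up for the pro-B cell programme (2.20, adjusted p = 3.5e-21, and 0.65 with an estimated correlation), hepatocyte markers (1.39, 0.00051, and 0.65) and MHC class II genes (1.09, 0.00041, and 0.65). It moved down for myeloid markers (-2.26, 7.7e-07, and 0.65), erythroid markers (-2.01, 7.9e-08, and 0.65), ribosomal protein genes (-0.81, 7.9e-09, and 0.65), cell cycle genes (-0.63, 0.0029, and 0.79) and oxidative phosphorylation genes (-0.46, 0.0031, and 0.65). Each E15.5 and neonatal effect rests on 1 library per lineage, so a feature of 1 library would move a whole list.

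Plasmacytoid dendritic cell markers were lower in B-1 than in B-2 progenitors, 16 of 17 of them in all 4 sets. Chance gives 6.25% for a single gene. The markers vary together, so the 16 are not independent results and the count is not a test. The share of all tested genes that were lower in all 4 sets is not given here. Siglech was at 72 to 232 FPKM in the B-2 libraries, Bst2 at 54.1 to 321 and Tcf4 at 473 to 1190, and Tcf4 was also at 180 to 216 in B-1. A difference in depth was excluded. The B-1 libraries were deeper on average, though not at week 11 (mean log2 difference in total reads 0.25, and at most 0.74 between any 2 libraries). The markers' median log2 change in reads (0.5 added, not scaled to depth) was -4.96 (quartiles -5.34 and -3.20). Cells of another type in the B-2 gate are a candidate explanation. Other genes that were higher in B-2 could come from the same cells, which was not tested. Of the markers' variance between the 4 B-2 libraries, 52.4% was common to all of them, above all of 10000 random lists (median 5.8%). Those lists were matched by expression level only. Markers that vary together within the progenitors would also exceed them, so the share cannot tell the 2 apart. Of the 18 listed genes, 3 (Ccr9, Irf7, Sell) are in other lists too. Lineage-negative CD93+ sorting would remove cells of another type only if an antibody marks them, and the progenitors' own expression stays open, untested.

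Myeloid markers were higher in the adult libraries (median 2.42), most in B-2 week 9 (mean log2 CPM 9.32, against 7.05 in B-2 week 11, 7.68 in B-1 week 9 and 6.66 in B-1 week 11). S100a8 was at 3160 FPKM in B-2 week 9 and 567 in B-2 week 11, and Lyz2 at 8000 and 1520. Depth was excluded. The adult libraries were shallower on average (mean log2 difference -0.19), though B-1 week 9 was deeper than most liver libraries. Any 2 libraries differed by at most 0.74, while the markers' median log2 change in reads was 4.18 (quartiles 2.05 and 5.72). RNA of myeloid cells is a candidate explanation. Of the genes' variance between the 4 adult libraries, 57.7% was common to all of them (random median 3.6%). Genes that vary together within the sorted cells would also exceed random lists, so the share cannot tell these apart. Lineage-negative sorting with myeloid antibodies would remove myeloid cells but not free RNA, 4 of the 24 listed genes are in other lists, and stage, tissue and sex stay open, untested.

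Other splits were counted for the comparisons of 4 against 4 libraries. For B-1 against B-2 as pairs, the 8 splits that part every pair are too few for a share under 0.05 (1767 calls in the real one, highest other 0). For adult against liver, the 18 splits with 2 libraries of each lineage on each side are too few as well (290 in the real one, highest other 250, with B-1 week 9 and B-1 neonatal exchanged).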

How the results depend on the processing

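Chosen after seeing the data were the settings with 16 columns, CPM, limma-voom and libraries or sets left out, and every setting of the 2 added comparisons. Values are counts of called genes, and the cause of a change was not tested unless stated. B-1 against B-2 is named by its stage.

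A pseudocount of 0.1 gave 54 at E15.5, 1 for neonatal against E15.5 in B-1, and 73 (B-1) and 54 (B-2) for adult against neonatal. Without the filter there were 0 at E15.5, 826 in the neonate (135 shared), 0 in the adult, 42 (B-1) and 40 (B-2) for adult against E15.5, 175 and 389 for neonatal against E15.5, 180 and 574 for adult against neonatal, 353 for the difference neonatal minus E15.5, 948 for the 4 sets as pairs and 115 for adult against liver. The stricter filter gave 33 at E15.5 and 50 for adult against neonatal in B-2. Quantile normalization gave 28 at E15.5, 2 for neonatal against E15.5 in B-1 and 47 for adult against neonatal in B-2. Without the trend there were 0 at E15.5 and 1 for neonatal against E15.5 in each lineage. Robust moderation gave 85 at E15.5, 40 (B-1) and 33 (B-2) for adult against E15.5, 2 and 1 for neonatal against E15.5, and 38 and 91 for adult against neonatal.

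Stage or week as a block gave 115 at E15.5, 1039 in the neonate and 886 in the adult. The 16 columns as separate samples gave 3061, 6075 and 5235 at the 3 stages, 3891 (B-1) and 5162 (B-2) for adult against E15.5, 4636 and 2214 for neonatal against E15.5, 3312 and 5477 for adult against neonatal, and 1024 and 2806 for the differences adult and neonatal minus E15.5. This follows from counting repeats of 1 library as samples. CPM of recovered reads gave 58 at E15.5, 43 for adult against neonatal in B-1, 25 for adult against E15.5 in B-2, 1 for neonatal against E15.5 in B-2 and 454 for adult against liver. Limma-voom gave 2 at E15.5, 212 in the neonate, 1 (B-1) and 3 (B-2) for adult against E15.5, and 0 and 1 for adult against neonatal. Only the groups compared gave 13 (B-1) and 0 (B-2) for adult against E15.5, and 0 for adult against neonatal in B-2. Adult against liver gave 78 without the week 9 libraries and 51 without the E15.5 libraries, with fewer samples. With an estimated correlation 0 of 132 list results passed. That test had little power here, and the Y-linked genes, at 0 in all adult libraries, failed it too.

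Leaving out 1 column or library gave 0 to 34 at E15.5, 0 to 527 in the neonate, 0 to 590 in the adult, 0 to 23 (B-1) and 0 to 43 (B-2) for adult against E15.5, 0 to 46 and 0 to 79 for adult against neonatal, 0 to 2 in each lineage for neonatal against E15.5, 0 to 1 for both differences, 567 to 1788 for the 4 sets as pairs, and 104 to 854 for adult against liver. List results were 130 to 136 with 1 column left out. Without 1 adult library the spread rests on 1 residual degree of freedom. With 1 column left out alone, the stage counts were 0 to 6, 433 to 513 and 504 to 578.

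Median-of-ratios scaling kept every count within 1.5 times. The adult B-1 against B-2 count was 545 to 659 under the pseudocount, the stricter filter, both scalings, no trend, robust moderation, CPM, limma-voom and only the groups compared. Of 12215 values of named genes under alternatives, 11084 kept their side of the threshold, 1080 lost and 51 gained the call. Among values called in the main or the alternative fit, 0 reversed direction, changes that rounded to 0 aside. Direction was not compared for values called in neither. Among the alternatives chosen beforehand, 8 group means and week 9 or week 11 alone left no residual degrees of freedom, a random block could not be fitted, only the groups compared gave no value without an adult group, and the count model was not run. Few reads lay behind some calls: under 30 reads per library in the higher group were behind 0 of 5 at E15.5, 5 of 463 in the neonate, 14 of 555 in the adult, 2 of 21 (B-1) and 2 of 16 (B-2) for adult against E15.5, and 3 of 9 and 3 of 27 for adult against neonatal.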

Other observations

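Both tests in this part on gene length were chosen after the result was seen.

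The lengths implied by FPKM and recovered reads did not follow annotated gene length. Sorl1 had the highest mean FPKM but ranked 916 by reads, with an implied length of 2 bases against an annotated 11321, and Gpi1 had 3 against 6452. Another definition of length was excluded, since the highest Spearman rho with the longest, shortest or coding length was 0.0128 across 7941 genes. Lengths joined by row position to a list of all genes in identifier order are a candidate explanation: in 77% of 61 windows of 300 genes, a small offset gave more lengths within 5% than any of 1000 far offsets (median 26.7% against 8.1% in those). This held in all 45 windows up to row 13500, where the offset reached -54 of the 60 searched, and in 2 of the 16 later ones, for which the explanation stays open. A gene's ratio between libraries does not depend on its length, and no biological explanation was tested.

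Weeks 9 and 11 differed by a fold of 2 or more for 642 genes in B-1 and 1131 in B-2. The differences of the lineages had a Pearson r of 0.43 across 11188 genes, which are not independent replicates.

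Neonatal B-2 cells had the lowest values of the pro-B cell genes Pax5 (0.476 FPKM, against 7.53 to 24.4 in the other B-2 libraries) and Ebf1 (291, against 470 to 1160).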
